A study of Mus musculus with 6 samples.

How the data were processed

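Nuclear RNA was measured by time-lapse SLAM-seq in female mouse embryonic stem cells of a 129S x Cast hybrid background. SLAM-seq feeds cells the uridine analogue 4-thiouridine (4sU), alkylates it in the extracted RNA with iodoacetamide, and reads labelled RNA from T-to-C (T>C) conversions in the sequence. Per the labels, the promoter of the endogenous Xist gene had been replaced with a doxycycline-inducible one on the 129S allele, and Bgl stem-loops had been placed at the 3' end of Xist. Cells received 1 µg/ml doxycycline for 17.5 to 20 h, then 500 µM 4sU with doxycycline for 4 h, then medium with 50 mM uridine and doxycycline for 0, 30, 60, 90, 120 or 150 min. Start times were staggered so that all cultures were collected together. Nuclei were isolated after the cells had been pre-plated to remove feeder cells, and 1 µg RNA per sample went into stranded total RNA libraries read as paired ends of 81 nt.

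The deposited table held 1 library per washout time and 23281 genes. Its column names carried a number without a unit, or none, and the time of each column was inferred: each number was read as the washout time in the sample titles without their shared ending, and columns with no number as 0 min. Every slope on time rests on that reading. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to the mouse build mm10; the program behind the per-gene table and its annotation release are not given in the sources used here. Per the file headers, the table gave read counts per gene, not normalized, and counts of T>C conversions and of covered T positions, which were printed with 4 significant digits. Per the file headers, the authors also gave the labelled fraction of each gene's reads as a posterior mean, a posterior mode, and 5% and 95% quantiles. How the authors set the conversion rate behind that fraction is not given in the sources used here. Gene IDs were matched to the GENCODE M21 annotation of the same build, and 23223 genes (99.75%) matched. Strand use in the counting is not given in the sources used here, so overlapping antisense genes and multicopy families such as histones and ribosomal proteins carry that uncertainty. Tsix and the mitochondrially encoded genes were not analysed here.

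Total reads per library were 28535162, 20664103, 26072700, 21638379, 26056531 and 18558073 for 0, 30, 60, 90, 120 and 150 min. With 1 library per time there were no replicates, so time entered each model as a number, which left 4 residual degrees of freedom. P-values measure the scatter of these 6 libraries around a line in time and not a spread between cultures. Posterior quantiles cover the uncertainty of the fraction within 1 library only.

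The decay rate was the least-squares slope of the natural log of the labelled fraction on washout time, and the half-life was ln 2 divided by that rate. Because the RNA came from nuclei, these values describe loss of label from nuclear RNA. Decay and export from the nucleus were not told apart. For Xist, the 720 orderings of the times gave an exact two-sided permutation p, whose smallest possible value is 0.00278. Across genes, limma 3.58.1 tested the slope for the 11462 genes with a mean of at least 100 reads and a fraction above 0 in all libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Total read counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) for a slope on time. Gene lists were tested against all other genes with camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, on ln fraction and on log2 CPM (counts scaled to library size) with a prior count of 2. A second estimate of turnover used the fraction at 0 min alone, as the half-life that gives that fraction after 4 h of labelling at steady state. No paired analysis was possible because each time had 1 library.

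On simulated data with the scatter of the real libraries, 81 of 100 genes with a half-life of 60 min were recovered. Of 100 genes with 120 min, 10 were recovered, among 11462 genes and with 3 false calls. Only 100 genes per half-life declined in that simulation, which makes the adjusted threshold stricter than where many genes decline. For total counts, 58 of 100 genes changed 2-fold over 150 min and 90 of 100 changed 4-fold were recovered among 15541 genes, with 7 false calls. In both simulations the scatter was drawn independently for each gene. The false calls therefore do not cover deviations of a library that many genes share.

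The 21 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from alternatives named as added. The rule took Xist, Tsix, Jpx, Ftx, Malat1 and Neat1 where measured, then the 8 shortest and 8 longest half-lives among genes with a called decline and a mean of at least 500 reads. From each list with at least 5 measured members it took the 2 shortest and 2 longest half-lives among called members. For total counts it took the 8 largest rises and falls and up to 2 members per list past the threshold. Gene models with clone or Gm-number names were counted and not named unless a list held them, as it did Gm26917. Gm42418 is named outside the rule, for its share of reads, and was chosen after its values were seen. Alternatives were leaving out each library, the logit scale, the posterior mode, the T>C rate per covered T, labelled abundance with 2 scalings, weights from the posterior, a nonlinear fit, a background, other read minimums (30, 300 and none), moderated variances with a trend, and DESeq2 1.42.0 for counts. Analyses ran in R 4.3.3 and Python 3.11.15.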

Results

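The half-life of Xist, the long noncoding RNA that coats and silences one X chromosome in female cells, was the question of the experiment. Embryonic stem cells induced to express Xist were labelled with 4sU, moved to medium with excess uridine, and collected after 0, 30, 60, 90, 120 or 150 min, with 1 nuclear RNA library per time and no replicates. Libraries held 18558073 to 28535162 reads. Xist (ENSMUSG00000086503; X, 103460366 to 103483254 in mm10, minus strand, annotated as a lincRNA with 17769 nt in the deposited table) received 23378 to 32597 reads per library.

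Labelled Xist declined over the washout. The labelled share of Xist reads was 61.2% at 0 min (posterior 5% to 95% range 60.7 to 61.6), 51.4% at 30 min, 60.3% at 60 min, 43.9% at 90 min, 32.0% at 120 min and 26.9% at 150 min (26.3 to 27.4). The decay rate was 0.335 ± 0.071 per h (SE, 6 libraries), a half-life of 124 min, with 103 to 158 min at 1 SE to either side. The natural log of the share was correlated with time over the 6 libraries (Pearson r = -0.92, two-sided exact permutation p = 0.0111, adjusted p = 0.0194 over 2 relations). Spearman rho was -0.94 (two-sided exact permutation p = 0.0167, adjusted p = 0.0333). Without the 0 and 150 min libraries the Pearson r was -0.83. The exact permutation p was 0.05 without the 0 min library (half-life 108 min) and 0.0667 without the 150 min library (143 min), neither under the threshold. The value depended on the measure, since the raw T>C rate of Xist, which went from 6.13% to 1.33%, gave a half-life of 70.1 min. On the logit of the share, ln 2 over the slope was also 70.1 min. That is a halving time of the odds of label and not a half-life of labelled RNA.

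**Figure D1:**
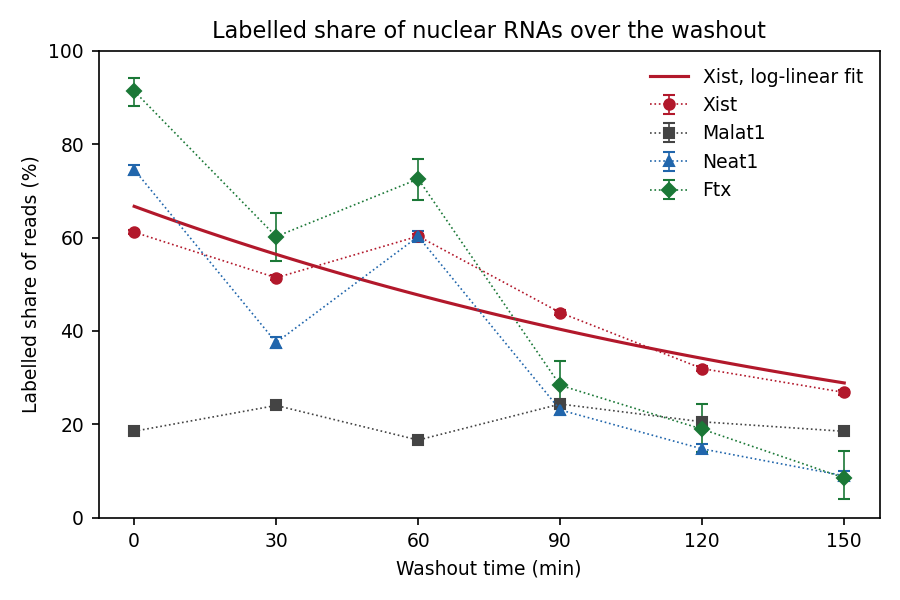
Labelled share of reads (%) against washout time (min) for Xist, Malat1, Neat1 and Ftx, 1 library per time. Bars are the authors' 5% and 95% posterior quantiles, dotted lines join the libraries and the solid line is the log-linear fit to Xist; Xist went from 61.2% to 26.9%, Neat1 and Ftx ended at 9.0% and 8.55%, and Malat1 was at 18.5% at both ends.

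Other nuclear noncoding RNAs lost label at very different rates. Ftx, a noncoding neighbour of Xist in the X inactivation centre, fell from 91.4% to 8.55% labelled with a half-life of 44.8 min (39.9 to 51.0 at 1 SE; limma adjusted p = 5.12e-05). Neat1, the scaffold of paraspeckles, fell from 74.6% to 9.0%, a half-life of 50.8 min (limma adjusted p = 6.27e-05). Malat1, an abundant nuclear speckle RNA, was 18.5% labelled at 0 min and 18.5% at 150 min, and no slope was detected (limma adjusted p = 0.968). Its raw T>C rate was 1.80% at 0 min, 1.17% at 120 min and 0.96% at 150 min, a slope that did not pass either (limma adjusted p = 0.176). Of 17 measured nuclear and regulatory lncRNAs, 14 fell and 0 rose by limma, and 14 fell and 1 rose when adjusted over the list alone. Dancr had the shortest half-life among them (44.0 min) and Lncenc1 the longest (151 min), with Xist next to it. The list as a whole missed the threshold against other genes (camera adjusted p = 0.0534, and adjusted p = 0.742 with an estimated correlation), and passed with the preset correlation without the 30, 60, 120 or 150 min library (0.0263, 0.042, 0.047 and 0.0151). It also passed with posterior weights (0.00629), on labelled abundance (0.0483 with TMM, 0.0409 without), with the 30 and 60 min times exchanged (0.0315) and without both of those libraries (0.0224). Jpx, another noncoding gene of the X inactivation centre, had 8 to 33 reads per library and was below the read minimum.

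Across the transcriptome, 5996 of 11462 genes (52.3%) lost label and 136 gained it by limma, at a Benjamini-Hochberg adjusted p under 0.05. The median half-life of the genes that fell was 86.9 min (interquartile range 63.0 to 122; jackknife SE over libraries 16.4 min), and 1289 of them had a half-life under 60 min. Of the genes that fell, 76.1% had a shorter half-life than Xist, but the test removes slow RNAs. The RNA was nuclear, so this ranking does not tell decay from export out of the nucleus. Over all 11462 genes tested Xist lost label faster than most, at rank 4563.5 from the fastest and 0.335 per h against a median of 0.247 per h. The fastest RNAs included Mir17hg, the host of the miR-17 cluster (28.2 min; 88.4% labelled at 0 min and 1.86% at 150 min), Fgf4, the growth factor that primes stem cells for differentiation (29.3 min), Nodal (31.7 min), the Mediator subunit gene Med26 (31.7 min), the immediate early gene Ier2 (31.8 min) and the pluripotency factor Klf2 (31.8 min). Their adjusted p by limma was 5.12e-05 each. At the slow end stood Mtfr1l (191 min), Polg, the mitochondrial DNA polymerase (192 min), Atp4b (192 min), the metallothionein Mt1 (193 min), the RNA-binding protein gene Elavl1 (193 min), the nuclear exosome subunit Exosc10 (193 min), the phosphate carrier Slc25a3 (193 min) and Def8 (194 min). These slow values lie at the detection limit, because genes with smaller slopes did not pass the test. Without the 150 min library 3582 genes fell, with libraries weighted by the posterior 2945 did, and with the same weights not scaled within genes 0 did. On the logit scale the median of ln 2 over the slope was 48.7 min, a halving time of the odds of label and not of the share.

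Zinc finger, immediate early, histone, splicing and p53 target genes lost label faster than other genes by camera with the preset correlation only (adjusted p = 1.19e-20, 1.75e-09, 3.36e-08, 0.000592 and 0.00188). None of these 5 calls held with an estimated correlation (adjusted p = 0.742 for each with an estimated correlation). By exact permutation of the times none held after adjustment (smallest adjusted p over the 20 lists = 0.0695). Of 302 zinc finger genes, taken by the symbol Zfp and a number and mostly C2H2 DNA-binding proteins, 290 fell (292 adjusted over the list alone) and 1 rose, and Zfp39 (28.3 min) and Zfp574 (29.7 min) were the shortest-lived. Of 40 immediate early and growth factor response genes 39 fell (39 adjusted over the list alone), from Ier2 and the ERK phosphatase Dusp6 (33.6 min) to Etv5 (150 min) and Maff (183 min). Of 55 replication-dependent histone genes 52 fell (52 adjusted over the list alone), among them Hist1h3g (44.8 min), Hist2h2ab (45.5 min), Hist2h2bb (157 min) and Hist4h4 (169 min). Of 31 splicing factors of the SR group and CLK kinases 25 fell (28 adjusted over the list alone), with Rsrp1 (42.3 min) and Clk1 (43.0 min) ahead of Srsf3 (130 min) and Ddx5 (135 min). Of 25 p53 targets 22 fell (24 adjusted over the list alone), led by Mdm2, the ubiquitin ligase that restrains p53 (55.0 min), and the cell cycle inhibitor Cdkn1a (57.6 min), with Rrm2b (147 min) and Zmat3 (160 min) slowest. The p53 target list also missed the threshold with libraries weighted by the posterior (camera adjusted p = 0.125).

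OXPHOS subunits, ribosomal proteins, glycolysis enzymes, translation factors and feeder markers had lower decay rates than other genes by camera with the preset correlation only (adjusted p = 1.37e-12, 6.02e-05, 1.65e-05, 0.000592 and 9.27e-06). None of these 5 calls held with an estimated correlation either (adjusted p = 0.742 for each with an estimated correlation). In the same order the median decay rates were -0.027, 0.063, -0.091, 0.039 and -0.052 per h, so the lists with negative values did not lose label at the median. Of 74 genes listed as OXPHOS subunits encoded in the nucleus 5 fell and 2 rose (0 and 0 adjusted over the list alone). Their median labelled share was 14.4% at 0 min and 14.3% at 150 min. Cox6b2 (117 min) and Atp5l (131 min) were the shortest-lived list members that fell. Atp5sl (147 min), which is not itself a subunit, and Atp5e (153 min) were the longest. Of 81 cytosolic ribosomal protein genes 8 fell (4 adjusted over the list alone), including Rpl10a (72.6 min), Rpl22l1 (84.5 min), Rpl10l (179 min) and Rpl27a (190 min). Of 18 glycolysis enzymes 2 fell, Hk2 (98.2 min) and Eno2 (99.9 min), and 2 adjusted over the list alone. Of 34 translation factors 5 fell (4 adjusted over the list alone), with Eif1a (55.5 min) and Eif4a2 (76.2 min) the shortest-lived and Eif1 (93.3 min) and Eif3a (174 min) the longest. Of 20 fibroblast feeder cell markers 3 fell (2 adjusted over the list alone), Twist1 (99.1 min), Twist2 (124 min) and Pdgfra (178 min). On labelled abundance in place of the labelled share, glycolysis and ribosomal proteins missed the threshold (camera adjusted p = 0.101 and 0.187 with TMM, 0.0949 and 0.131 without).

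**Figure D2:**
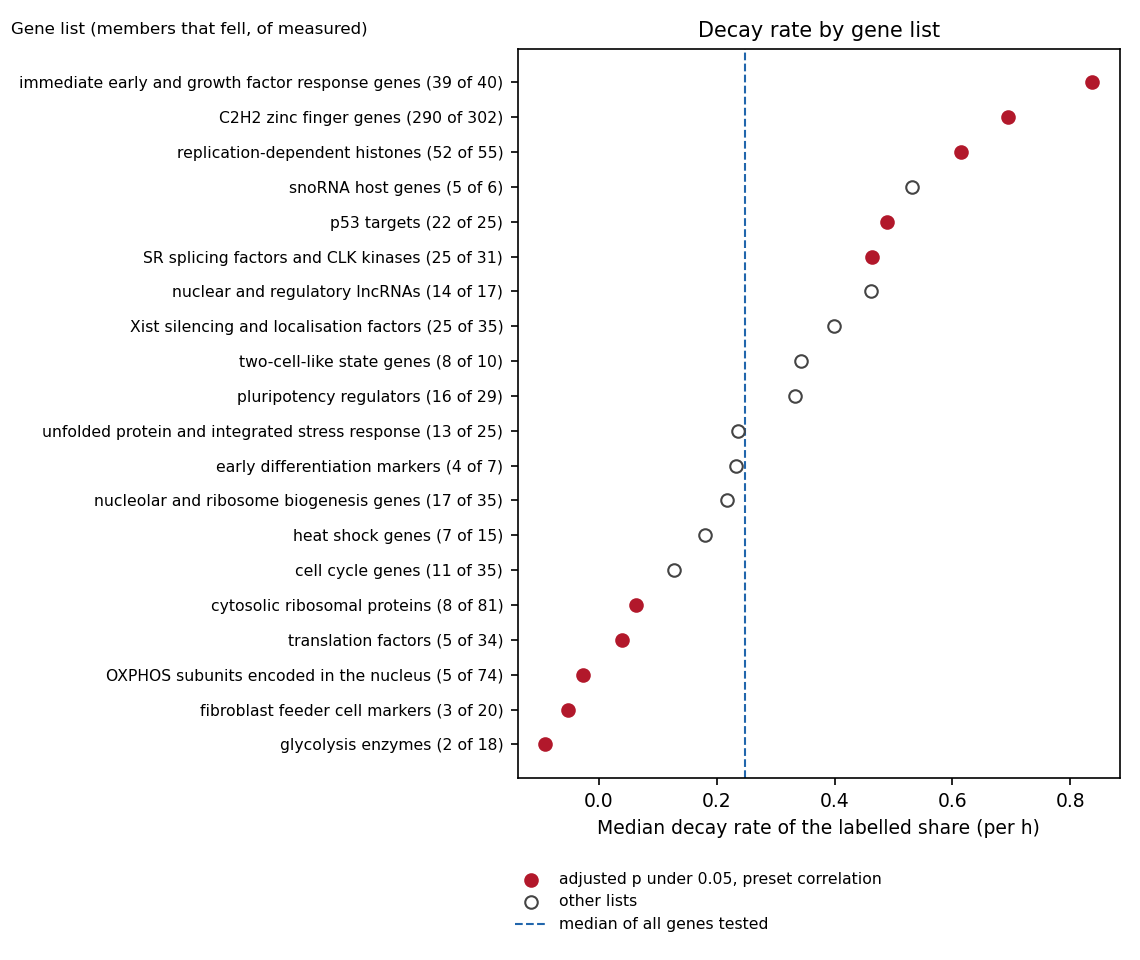
Median decay rate of the labelled share (per h) for the 20 gene lists tested, with the number of members that fell of those measured. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, none did with an estimated one, and the dashed line is the median of all genes tested, 0.247 per h; lists run from 0.837 per h for immediate early genes to -0.091 per h for glycolysis enzymes.

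The remaining lists, those of Xist function and of pluripotency among them, did not pass against other genes. Of 35 Xist silencing and localisation factors 25 fell (25 adjusted over the list alone), with the m6A writer subunits Cbll1 (49.6 min) and Rbm15 (52.9 min) fast and the Polycomb subunits Pcgf3 (162 min) and Suz12 (169 min) slow (camera adjusted p = 0.0532, and adjusted p = 0.856 with an estimated correlation). With the preset correlation the Xist factors passed without the 90 min library (0.0446), on the logit scale (0.0485), with posterior weights (0.0203) and at a minimum of 300 reads (0.0379). Of 29 pluripotency regulators 16 fell (16 adjusted over the list alone), between Fgf4 and Klf2 at one end and Stat3 (125 min) and the X-linked Nr0b1 (157 min) at the other (camera adjusted p = 0.468). Of 6 snoRNA host genes 5 fell (6 adjusted over the list alone), with Rabggtb at 68.2 min, Snhg12 at 71.0 min, Snhg20 at 83.8 min and Snhg11 at 147 min (camera adjusted p = 0.0983, and adjusted p = 0.742 with an estimated correlation). With the preset correlation the snoRNA hosts passed without the 150 min library (0.0349) and with libraries weighted by the posterior (0.00142). Of 25 unfolded protein and integrated stress response genes 13 fell (13 adjusted over the list alone) and 1 rose, with Atf4 (42.8 min) and Xbp1 (50.4 min) fastest, Atf3 (97.0 min) and Vldlr (176 min) slowest (camera adjusted p = 0.907). Of 15 heat shock genes 7 fell (5 adjusted over the list alone), Dnajb1 (58.1 min) and Dnajb4 (63.2 min) first, Hspa8 (184 min) and Dnaja1 (185 min) last (camera adjusted p = 0.451). Of 35 nucleolar and ribosome biogenesis genes 17 fell (17 adjusted over the list alone), from Ppan (46.1 min) and Rrs1 (50.2 min) to Gar1 (176 min) and Polr1a (187 min), with a camera adjusted p of 0.885. Of 35 cell cycle genes 11 fell (10 adjusted over the list alone), from Cdc25a (44.3 min) and Cdc6 (52.8 min) to Rrm2 (160 min) and Plk1 (175 min), with a camera adjusted p of 0.142. Of 7 early differentiation markers 4 fell (4 adjusted over the list alone), Otx2 (55.4 min), Eomes (56.0 min), Meis1 (88.6 min) and Pdgfra, with a camera adjusted p of 0.907. Of 10 two-cell-like state genes 8 fell (8 adjusted over the list alone), from Zfp352 (70.8 min) and Tmem92 (82.2 min) to Usp17lc (130 min) and Zscan4d (149 min), with a camera adjusted p of 0.266. Exact permutation of the times on each list's median against all genes gave p from 0.0111 upward, under 0.05 before adjustment for 12 of the 20 lists. None of the 20 lists passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.0695).

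Turnover of Xist was also estimated from the label taken up before the washout. The 61.2% labelled after 4 h gave a half-life of 176 min for Xist at steady state, against 124 min from the washout. Over the 5996 genes that fell, the medians were 144 min from uptake and 86.9 min from washout, and the Spearman rho across genes was 0.794. Both estimates use the 0 min library, and the genes were selected for a slope and are not independent replicates. With the washout fitted without the 0 min library, so that no library was shared, rho was 0.757 over the 5659 genes that then fell. Mdm2 had 56.3 min from uptake and 55.0 min from washout, whereas Neat1 had 122 and 50.8 min and Rpl10a had 598 and 72.6 min.

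The library read as 60 min stood above the library read as 30 min in T>C rate, and in labelled share for most of the genes that fell but not for most genes. The T>C rate over all genes was 4.05, 2.69, 4.11, 2.57, 1.55 and 1.17% in time order, and where both mates covered a base it was 4.58, 2.80, 4.72, 2.69, 1.54 and 1.12%. Over all genes tested, 47.1% had a higher labelled share at 60 than at 30 min, and the median share was 45.8% at 30 min and 44.5% at 60 min. Of the genes that fell, 77.0% had a higher share at 60 min, Xist, Neat1, Ftx and the fast regulators Fgf4 (58.4% and 80.4%), Ier2 (38.4% and 69.8%) and Mdm2 (61.8% and 82.9%) among them. With these times exchanged, an alternative added after seeing the data, 6242 genes fell and the half-life of Xist was 118 min. Without both libraries, also added, 5392 genes fell and Xist had 127 min.

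**Figure D3:**
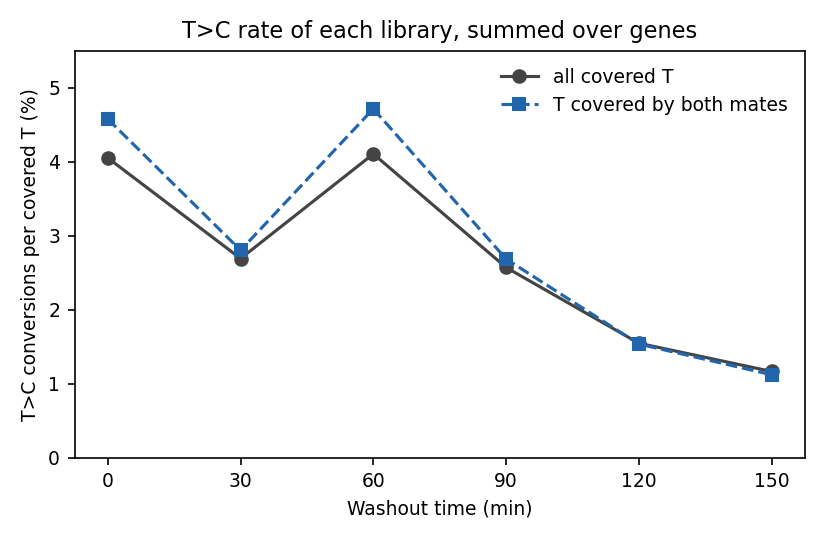
T>C conversions per covered T (%) in each library against washout time (min), summed over genes. Circles count all covered T and squares only T covered by both mates; the 60 min library reaches 4.11% and 4.72%, above the 30 min library at 2.69% and 2.80%.

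Total RNA was compared over the washout because a half-life from a labelled share takes levels as constant. Scaled reads show a gene relative to the rest of its library, so they cannot show whether absolute levels were constant. Xist had 1099, 1137, 1147, 1120, 1265 and 1394 CPM (reads scaled to library size with TMM) in time order, a slope of 0.12 ± 0.063 log2 per h (SE) that did not pass in edgeR (adjusted p = 0.27). Xist level and time had a Pearson r of 0.86 (exact permutation p = 0.0194, adjusted p = 0.0194 over 2 relations; r = 0.69 without the 0 and 150 min libraries) and a Spearman rho of 0.83 (exact permutation p = 0.0583, adjusted p = 0.0583). On labelled abundance in place of the labelled share, Xist had a half-life of 166 min with TMM. Of 15743 genes, 0 passed edgeR, although 3416 had an unadjusted p under 0.05 (1813 of them rising), and DESeq2 called 650 (309 rising). The count of 0 rested on the libraries at hand, since edgeR called 1413 genes without the 60 min library, 41 without the 0 min library and 2 without the 30 min library. With the 30 and 60 min times exchanged it called 2884, of which 1590 rose.

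Among p53 targets, 22 of 25 had lower total reads later in the washout by point estimate, 14 passed when adjusted over the list alone and 0 passed over all genes. Mdm2 went from 494 CPM at 0 min to 665 at 60 min and 125 at 150 min, and Cdkn1a from 111 to 133 and 35.5 (edgeR adjusted p = 0.0985 and 0.0844 over all genes). The list was lower than other genes by camera (adjusted p = 3.89e-05, and adjusted p = 0.711 with an estimated correlation). Negative slopes were found for 81 of 82 ribosomal protein genes, 77 of 77 genes listed as OXPHOS subunits and 17 of 19 glycolysis enzymes. Their camera adjusted p was 9.72e-08, 7.42e-07 and 8.34e-05, with 0, 0 and 5 members passing when adjusted over the list alone. These 3 calls were lost with an estimated correlation (adjusted p = 0.711 for each with an estimated correlation). Positive slopes were found for 272 of 348 zinc finger genes, 23 of 32 splicing factors and 28 of 35 Xist silencing and localisation factors (camera adjusted p = 2.03e-07, 0.00839 and 0.00781), with 0, 2 and 0 passing when adjusted over the list alone. These 3 calls were lost as well (adjusted p = 0.711 for each with an estimated correlation), and splicing factors missed the threshold with the preset correlation without the 0 min library (camera adjusted p = 0.199) and without the 150 min library (0.0524). Library composition moved over the same libraries: in time order the noncoding gene Gm26917 took 5.32, 7.58, 5.71, 4.30, 8.17 and 8.02% of reads and Gm42418, named outside the rule after its values were seen, took 0.17, 0.53, 0.29, 0.37, 0.72 and 0.74%. Fibroblast feeder cell markers, with a median of 36.6 CPM, had 11 members higher and 12 lower (camera adjusted p = 0.884). The other 12 lists did not pass, although with 1 library left out immediate early genes (0.000143 without 150 min), histones (0.00178 without 0 min, 0.0292 without 150 min), stress response genes (0.0179 without 30 min, 0.0424 without 120 min) and two-cell-like genes (0.0253 without 150 min) had a camera adjusted p under the threshold. Stress response genes also did with the 30 and 60 min times exchanged (0.0276) and without both libraries (0.0124).

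**Figure D4:**
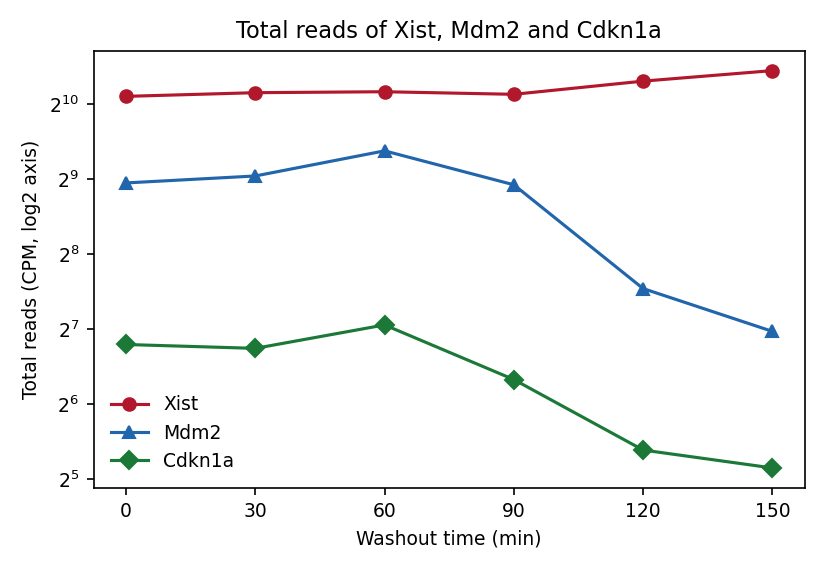
Total reads in CPM (log2 axis) against washout time (min) for Xist, Mdm2 and Cdkn1a, 1 library per time with no error bars. Xist lies between 1099 and 1394, while Mdm2 and Cdkn1a are highest at 60 min (665 and 133) and lowest at 150 min (125 and 35.5).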

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

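The exchanged times and the fits without both the 30 and 60 min libraries were chosen after the data were seen; all other alternatives were fixed before. No call for Xist, the lists or the named genes changed direction, but of 135 genes with a called rise in labelled share, 25.9% had a falling T>C rate. The half-life of Xist ranged from 108 to 143 min when each library was left out. Its exact permutation p was no longer under 0.05 without the 0 min (0.05) or the 150 min library (0.0667), where 5 times leave fewer orderings. Under the other settings p stayed under 0.05, with half-lives from 70.1 min (T>C rate) and 96.1 min (background subtracted) to 166 min (labelled abundance). The logit also gave 70.1 min, but as a halving time of the odds of label. Genes with a called decline numbered 3582 to 6335 with 1 library left out. Posterior weights gave 2945, and the same weights not scaled within genes gave 0. The scaling was meant to keep a common variance scale across genes, and the cause of these changes was not tested. The T>C rate gave 7664, and read minimums of 30, 300 and none gave 6808, 4664 and 6858. The median half-life was 70.1 to 93.6 min with 1 library left out, 62.5 min from the T>C rate and 108 min with weights. The ratio of T>C rate to labelled share was 10.3% at 0 min and 5.16% at 150 min (medians over 7540 genes). A ratio that is lower late makes the T>C rate fall faster than the share. Why the ratio was lower late, and the cause of the other shifts, were not tested. The 48.7 min on the logit scale is a halving time of the odds of label and not a half-life. An estimated correlation left 0 of 10 lists for decay and 0 of 7 for total reads, also with the times exchanged (0 and 0), against 9 to 12 and 7 to 9 lists under other settings. Genes with a trend in total reads numbered 0 to 1413 with 1 library left out, 399 with no filter, 650 with DESeq2, 2884 with the times exchanged and 559 without both libraries. The slope of Xist total reads stayed between 0.08 and 0.15 log2 per h and never passed in edgeR or DESeq2. With all libraries the Pearson correlation of Xist total reads with time did pass (exact permutation p = 0.0194). Of 89 genes taken by the naming rule, 41 lay on the same side of the threshold with posterior weights, 1 with those weights not scaled within genes, 48 without the 150 min library and 89 with the T>C rate. With 4 residual degrees of freedom, simulated half-lives of 120 min were recovered in 10 of 100 genes. Few genes declined in that simulation, so its adjusted threshold was stricter than in the data, where 5996 genes were called. It therefore does not give the share of slow RNAs detected here. Called half-lives had an upper quartile of 122 min and reached 197 min. No paired analysis was possible because each time had 1 library.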

Other observations

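Tests chosen only after the result was seen were those of the 60 min library on total reads (exchanges and the rotation) and on the mate overlap, and the placement of libraries on T>C rates or without the 90 min library. The fit without the 60 min library was a fixed alternative, but its use as a test for p53 targets was also chosen afterwards. The values around Xist, by gene type and for the rising genes were also taken up after the data were seen. Genes around Xist lost label faster than Xist itself by point estimate. Within 500 kb of Xist, 4 other genes passed the read minimum, and each of the 4 lost label by limma. Ftx had a half-life of 44.8 min, Nap1l2 64.8 min, Chic1 66.3 min and Rlim, the ubiquitin ligase that promotes Xist expression, 86.2 min, against 124 min for Xist. The differences between these genes were not tested. Of 89 annotated lincRNAs tested 66 fell and 2 rose, with a median half-life of 58.3 min and 74.6% labelled at 0 min, while of 11348 protein-coding genes 5921 fell and 133 rose, with a median of 87.1 min and 46.6% labelled.

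X-linked RNAs were asked about as a hypothesis, that they lose label at another rate than autosomal RNAs. The 395 X-linked genes without Xist had a median decay rate of 0.122 per h against 0.253 per h for the others, and 143 fell and 9 rose. Camera passed with the preset correlation (p = 0.000217) but not with an estimated one (p = 0.531), and the exact permutation of the times gave p = 0.0611, so the hypothesis did not pass both tests set for it. X-linked RNAs were also less labelled at 0 min, at a median of 32.8% against 47.2%. Xist, which silences an X chromosome, was induced before and during the labelling. Whether X-linked levels were constant, as a decay rate from the labelled share assumes, was not tested.

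The 136 genes whose labelled share rose went from a median of 9.58% at 0 min to 21.1% at 150 min, 0.312 per h on the log scale. Their T>C rate rose by a median of 0.043 per h, and fell for 25.9% of 135 of them. The ratio of T>C rate to labelled share, a median over 7540 genes, was 10.3, 6.82, 11.7, 7.26, 5.54 and 5.16% in time order.

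The first pattern weighed is the 60 min library lying above the 30 min library in the genes that fell. In bases read by both mates, 99.75% of these genes had a higher T>C rate at 60 than at 30 min. The higher T>C rate was thus not confined to bases read by 1 mate. This repeats the difference between the whole libraries (4.72 against 2.80% in such bases) and does not test the authors' fraction estimate. The ratio of T>C rate to labelled share was 6.82% at 30 min and 11.7% at 60 min, so a fault of that estimate stays open. An exchange of the 30 and 60 min libraries may be the cause: of the 15 ways to exchange 2 times, that one gave 2884 genes with a trend in total reads in edgeR and the exchange of 0 and 60 min gave 3099, while the other 13 gave 0, and a rotation of the first 3 times gave 4975. On decay lines through the other 4 libraries the labelled share put the 30 min library at 34.8 min (interquartile range over 4279 genes 28.9 to 41.4). It put the 60 min library at 18.4 min (upper quartile 23.7). The T>C rate put them at 54.5 min (49.8 to 60.0) and 4.59 min (upper quartile 10.2). Without the 90 min library the lines put that library itself at 57.3 min by labelled share and 64.9 min by T>C rate. In the same order, those lines put the 30 min library at 26.7 and 48.3 min and the 60 min library at 10.4 and -1.31 min. The scales differ and the lines misplace a library not in doubt, so an exchange, a rotation and a 60 min culture that was not fully washed cannot be told apart, and a real rise of labelled RNA between 30 and 60 min was not tested.

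The second pattern is the lower total reads of p53 targets late in the washout. Their median slope of -0.25 log2 per h lay below all of 10000 random lists matched on decay rate and read count (central 95% 0.019 to 0.14), which argues against a property of short-lived RNAs in general. Without the 60 min library the list still passed with the preset correlation (camera adjusted p = 0.000184). That argues against the 60 min library alone, though this use of the fit was chosen after the result was seen. With all libraries the call was lost with an estimated correlation (camera adjusted p = 0.711). Chance in the order of the times stays open, since 38 of the 720 orderings gave as large a correlation of the list's median (exact permutation p = 0.0528). A p53 response to 4sU that fades after its removal may also contribute, and the design, with no culture free of 4sU, did not test it.

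The count of 5996 genes that lost label was set against 100 orderings of the times, the labelled one included. Of these, 1 gave as many, the labelled order, and the highest of the others gave 4143, so a random order seldom gives so many. The labelled order is not the extreme one, because the exchange of 30 and 60 min, which was not among those drawn, gave 6242. The count of 4143 from another ordering may come from a structure shared by many genes across these 6 libraries. It may also come from an order close to the labelled one, which keeps part of a decline. These were not told apart.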
